A study of Drosophila melanogaster with 6 samples.

How the data were processed

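RNA was measured on 6 Affymetrix arrays of Drosophila melanogaster, 3 from Kc-167 cells treated with control double-stranded RNA against beta-lactamase and 3 from cells treated with double-stranded RNA against Enigma. Per the labels, cells were kept with 20 µg of double-stranded RNA in medium without serum for 1 hour, serum was added, the cells were harvested after 5 days, and 8 µg of total RNA entered the labelling reaction with biotin. The sample titles give each array its group and its replicate number. Nothing in the labels states that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision of every value.

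The deposited values were made with GCRMA, per the submitters' processing notes, and its version is not given in the sources used here. GCRMA corrects the background of each array, normalizes between arrays and summarises the probes of a probe set. The deposited values were taken as log2 expression values, from the method named and from their range of -0.32 to 14.30, since no label states the scale. They were used without further scaling. The table held 14010 probe sets, of which 44 Affymetrix control probe sets were left out of all tests. A probe set was tested where its log2 value was above 4 on at least 3 of the 6 arrays, which left 6975.

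Gene names came from GEO's annotation of the platform, which gave 1 gene for 12444 probe sets, several for 327 and none here for 1239. Symbols were checked through Entrez numbers against RefSeq genes of Release 6 plus ISO1 MT, where 12394 of the 12444 matched, and 0 symbols changed. Only probe sets with 1 gene were named. The array's annotation names no genome build, so no coordinates are given. The tested probe sets covered 5757 genes, and where a gene had several, its probe set with the highest mean over the 6 arrays stood for it in gene lists.

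Differences between the groups were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets as the threshold. Single probe sets are given as the log2 difference, Enigma RNAi minus control RNAi, with its standard error from this fit unless another is named. Enigma was also tested with an exact permutation test. The design before the data were examined had no block, with the replicate number as a block among the alternatives. The numbers were then checked for pairing: the deviations from the group means correlated at r = 0.80, 0.64 and 0.65 across probe sets for the arrays numbered 1, 2 and 3. The pairing comes from these values and from the numbers in the titles, not from a stated shared batch or day. Values with the block are printed where they change a call or a count.

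Gene lists were tested with camera of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the pathway lists, for lists with at least 5 genes tested. The lists were also tested with a correlation estimated from the residuals, in the other settings too, and, without and with the block, with fry. The 31 pathway lists were fixed before the data were examined: mitochondrial fatty acid beta-oxidation, oxidative phosphorylation, the tricarboxylic acid (TCA) cycle with pyruvate dehydrogenase, glycolysis, oxidative stress defence, glutathione S-transferases, cytochrome P450s with UDP-glycosyltransferases, cytosolic heat shock proteins, mitochondrial chaperones and proteases, the endoplasmic reticulum stress response, antimicrobial peptides with peptidoglycan recognition proteins, Toll and Imd signalling, JNK signalling, JAK-STAT signalling, insulin, TOR and FOXO signalling, lipid synthesis and storage, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, the proteasome, DNA replication, mitosis, apoptosis, autophagy and the lysosome, Notch signalling, the ecdysone response, the RNA interference machinery, serine, one-carbon and amino-acid response genes, aminoacyl-tRNA synthetases, cell adhesion, matrix and actin, metal handling, and the peroxisome. Marker lists for 10 cell types were fixed with them, as a family of their own: plasmatocyte, crystal cell, lamellocyte, fat body, muscle, neuron, glia, germline, gut epithelium and imaginal epithelium. Enigma was left out of every list, and 4 members matched no current symbol.

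The rule for named genes, also fixed before the data were examined, took Enigma and then the 12 largest rises and 12 largest falls among probe sets past the threshold whose 3 values per group did not overlap, or, with fewer than 5 such genes in a direction, the 10 with the smallest p in that direction as not passing. From each pathway list it took up to 4 members past the threshold, or, with none, the 2 with the largest difference. No probe set passed without the block, so the names without the block are those not passing. The 12 largest rises and falls with the replicate block are named as well, and this addition was made after their values were seen.

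The alternatives were other filters on low values, eBayes with trend and robust estimation, array weights, quantile, median and cyclic loess normalization of the deposited values, a floor at a log2 value of 4, the replicate block, each array left out in turn, stricter thresholds, 1 probe set per gene, and the mean of a gene's probe sets in the lists. The steps were tested on simulated data built from these arrays, with 6975 probe sets of which 100 were changed by a log2 value of 1 and 100 by a log2 value of 2. Without the block, the test recovered 74 and 93 of them, with 1 false call. With the block it recovered 96 and 100, with 10 false calls. The simulated noise was drawn independently for each probe set, and many large changes were planted. On the real arrays 32 probe sets differed by a log2 value of at least 1 in size. The recovered counts therefore do not measure the power of the test on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.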

Results

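Transcripts of Kc-167 cells, an embryonic Drosophila line with features of haemocytes, were profiled 5 days after RNA interference (RNAi) against Enigma or against beta-lactamase, a bacterial gene that flies lack. Enigma is gene CG9006, with the current symbol Egm, and encodes a mitochondrial protein related to acyl-CoA dehydrogenases, which catalyse the first step of fatty acid beta-oxidation. Each group had 3 arrays with replicate numbers 1 to 3, and a pair below is the control and the Enigma RNAi array of 1 number. Values are GCRMA expression values on the log2 scale, as mean ± SD with n = 3, and differences are Enigma RNAi minus control RNAi. The comparison asked which transcripts differ when Enigma is depleted.

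After Enigma RNAi the Enigma transcript was lower than in controls, at 3.65 ± 0.50 against 6.38 ± 0.36 (SD, n = 3), and at least 4.95-fold lower when values under the filter of 4 were raised to 4. Genes of detoxification were higher as groups, among them the glutathione S-transferases, with a median difference of 0.44 over 28 genes, and the cytochrome P450s with the UDP-glycosyltransferases, with a median of 0.29 over 31 that was 0.09 without control 3 (adjusted p = 0.475 with an estimated correlation for both lists). Genes of DNA replication and of mitosis were lower as groups, each with a median of -0.31, over 27 and 20 genes, at -0.19 without control 3 and -0.20 without Enigma 2 (adjusted p = 0.475 with an estimated correlation for both lists). In the same arrays the eIF4A signal at the 3' end over that at the 5' end, a sign of RNA quality, was higher by 0.33. Among single genes, the largest rise in the fit with the replicate number as a block was that of Ugt302K1, a UDP-glycosyltransferase, at 2.05 and at 1.17 without control 3, and the largest fall after Enigma was that of Echs1, an enoyl-CoA hydratase of beta-oxidation, at -1.10.

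The Enigma probe set was lower in all 3 pairs, with a difference of -2.72, a standard error of 0.29 and a 95% confidence interval of -3.41 to -2.04. This difference did not pass the threshold over all probe sets without the block (limma, adjusted p = 0.283), and it passed with the block (limma, adjusted p = 0.000118). The groups did not overlap, the Enigma RNAi values lay under the filter of 4 on 2 of 3 arrays, at 3.24 and 3.51, so that the difference was -2.31 with a floor at 4, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Of other genes of the acyl-CoA dehydrogenase family with a probe set here, a set chosen outside the rule once the main results had been seen, Arc42 differed by -0.17, CG4860 by -0.20, CG9547 by 0.04 and Acadvl by 0.14, and none passed with or without the block. CG6638 was below the filter for testing.

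Without the block, 0 of 6975 probe sets passed in limma. At an unadjusted p under 0.05 there were 297, 118 higher and 179 lower, against 348.75 expected by chance for unpaired arrays. The groups did not overlap for 8.97% of the probe sets, against 10% by chance for unpaired arrays, while 40.2% had the same direction in all 3 pairs, against 25%. Since the arrays pair by replicate number, 348.75 and 10% are too high as baselines. The other 3 ways to split the arrays 3 against 3 that part all 3 pairs had 5, 25 and 20 at an unadjusted p under 0.05, too few splits for a test. With the replicate block, 44 passed, 25 higher and 19 lower, representing 20 and 16 named genes, and 1347 had an unadjusted p under 0.05. All 44 had the same direction in the 3 pairs, while the values of the groups did not overlap for 18. The blocked count rested on the choice of arrays and processing: it was 586 without replicate 1, 2 without replicate 2 and 8 without replicate 3, and 1 with quantile normalization, with cyclic loess or with no filter, Enigma itself in each. With the replicate number as a random block it was 3. The blocked fit has few residual degrees of freedom, and fewer without a replicate. It then depends strongly on the variance that eBayes shares across probe sets, so 586 does not measure a gain in changed genes.

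**Figure D1:**
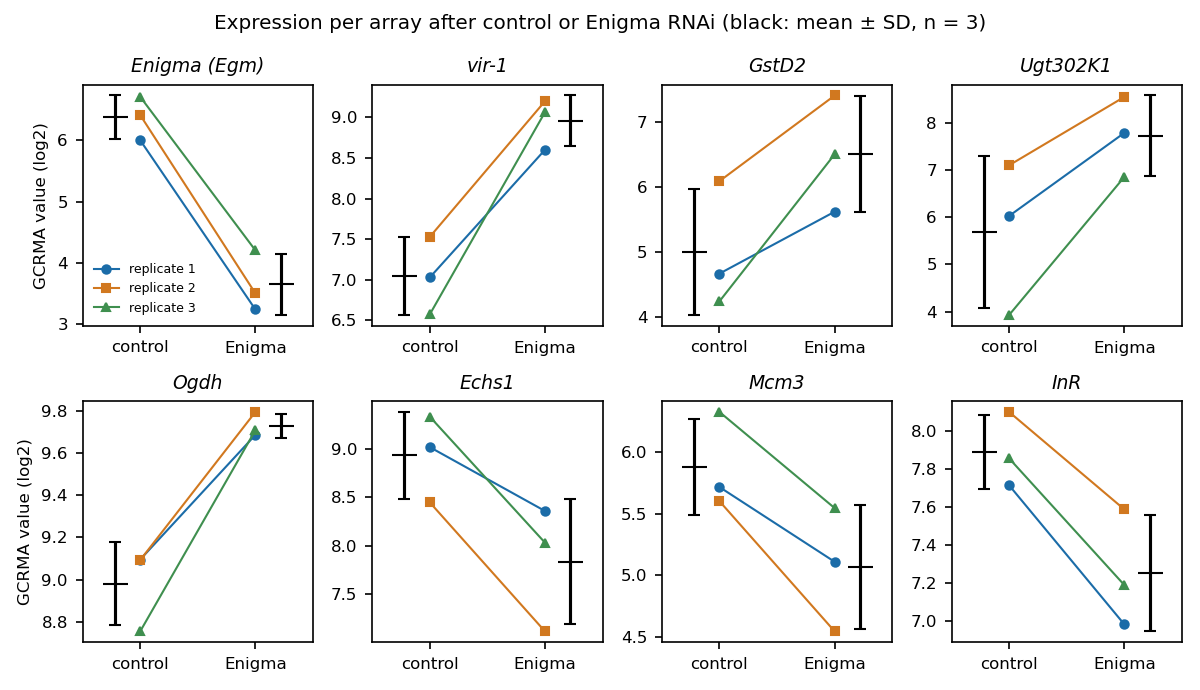
GCRMA expression on the log2 scale for 8 genes, with 1 point per array, lines joining the control and Enigma RNAi arrays of the same replicate number, and black bars for the mean ± SD (n = 3). Enigma was lower in each of the 3 pairs, with a mean difference of -2.72, and vir-1, GstD2, Ugt302K1 and Ogdh were higher in each pair while Echs1, Mcm3 and InR were lower in each.

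Among the genes that rose with the block were several enzymes that modify foreign compounds. Ugt302K1 rose by 2.05 ± 0.25 (SE of the blocked fit, adjusted p = 0.0297), from 5.69 ± 1.62 to 7.74 ± 0.85 (SD, n = 3), and was higher in 3 of 3 pairs. The glutathione S-transferases GstD2 and GstD10 rose by 1.51 and 1.12, the cytochrome P450 Cyp6d4 by 1.06 and the UDP-glycosyltransferase Ugt37C2 by 0.80. The virus-induced gene vir-1 rose by 1.91 ± 0.17 (SE of the blocked fit, adjusted p = 0.0180), from 7.04 ± 0.48 to 8.96 ± 0.31 (SD, n = 3), and its other probe set was higher as well, by 0.72. Further rises were those of CG5001 at 1.03, the zinc transporter gene foi at 0.97, EndoU at 0.87, Rcd2 at 0.86, the cuticular protein gene Cpr49Ac at 0.82 and the glutamine synthetase Gs2 at 0.81. Ogdh, a subunit of the 2-oxoglutarate dehydrogenase of the TCA cycle, rose from 8.98 ± 0.20 to 9.73 ± 0.06 (SD, n = 3). Without control 3 the differences were 1.17 for Ugt302K1, 0.60 for Cyp6d4, 0.48 for EndoU and 0.47 for Rcd2. The control mean of EndoU, 3.91, lay under the filter, and its difference was 0.58 with a floor at 4.

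Echs1 fell by 1.10 with the block, from 8.93 ± 0.45 to 7.83 ± 0.64 (SD, n = 3; limma with the block, adjusted p = 0.0339), and was lower in 3 of 3 pairs. The nicotinic acetylcholine receptor subunit gene nAChRbeta3 fell by 1.02, CG11788 by 0.88, CG7766 by 0.84 and wgn, a receptor of the tumour necrosis factor receptor family, by 0.82. Mcm3, a subunit of the replicative helicase, fell by 0.82, from 5.88 ± 0.39 to 5.07 ± 0.50 (SD, n = 3). Smaller falls were those of jigr1 at -0.77, Eato at -0.71, sip2 at -0.70, Kank at -0.69 and thoc7, a subunit of the THO complex of mRNA export, at -0.65. The insulin receptor gene InR fell by 0.64, from 7.89 ± 0.19 to 7.25 ± 0.31 (SD, n = 3). The probe sets of Eato did not give the same size, since its other one differed by -0.04. Without Enigma 2 the difference was -0.67 for nAChRbeta3 and -0.43 for Kank, and without control 3 it was -0.40 for sip2. That of wgn lay between -0.45 without control 1 and -1.25 without Enigma 1, and that of jigr1 between -0.44 without Enigma 2 and -1.16 without control 2.

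Without the block the 10 genes with the smallest p in each direction did not pass. Those with the higher mean after Enigma RNAi were vir-1, Cpr49Ac, Ogdh, CG30015, CG4630, GstE2, drongo, CG8301, GstE6 and the tetraspanin gene Tsp42Ee, with differences from 0.56 for CG8301 to 1.91 for vir-1. CG30015 differed by 0.74 on this probe set and by 0.06 on its other. Those with the lower mean were east, the kinetochore gene Nnf1a, spen, the RNA-binding protein gene Rbfox1, cue, l(1)G0320, CG1910, the flap endonuclease Fen1, Rbcn-3B and Acn, with differences from -0.44 for Rbfox1 to -0.65 for east.

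Of 29 pathway lists with at least 5 genes tested, 8 passed with the preset correlation, 5 higher and 3 lower after Enigma RNAi, and 0 passed with an estimated correlation or with fry. With the replicate block 9 passed, 7 of them shared with the 8. Adjusted over the list alone and without the block, 1 member passed in the TCA cycle list, Ogdh, and 0 in every other list, against 0 when adjusted over all genes tested. Control transcripts that report RNA quality differed between the group means as well. The eIF4A signal at the 3' end exceeded that at the 5' end by 1.38 ± 0.14 in controls and 1.71 ± 0.22 after Enigma RNAi (SD, n = 3), higher in 3 of 3 pairs, with an exact permutation p of 0.1. The same difference for actin was 0.65 ± 0.13 and 0.82 ± 0.18, also higher in 3 of 3 pairs, and for Gapdh 1.98 ± 0.12 and 2.06 ± 0.02, higher in 2 of 3, each with an exact permutation p of 0.4.

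**Figure D2:**
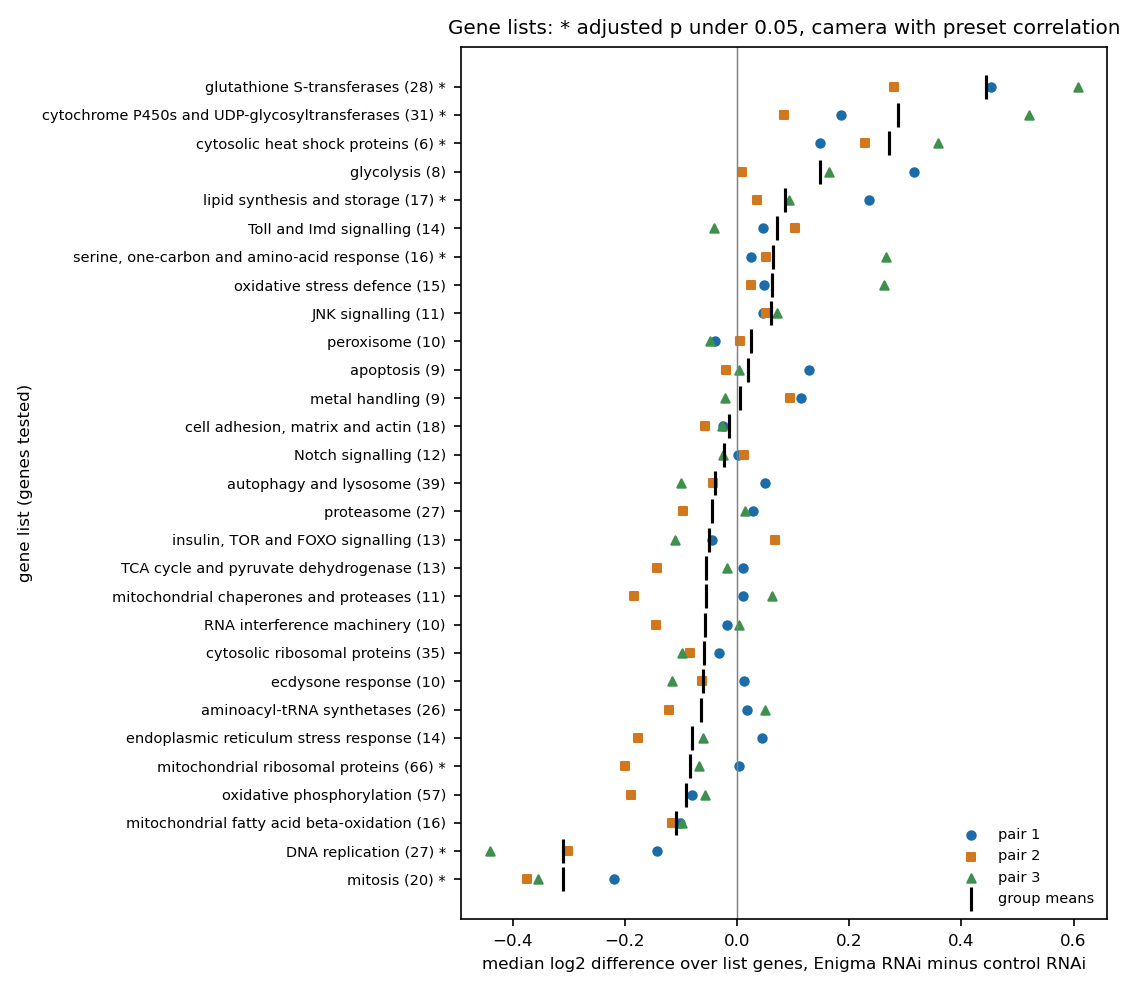
Median log2 difference, Enigma RNAi minus control RNAi, over the tested genes of each of the 29 pathway lists, with 1 coloured point per replicate pair, a black bar for the difference of group means, and an asterisk for an adjusted p under 0.05 with the preset correlation. Glutathione S-transferases lie to the right in all 3 pairs, at 0.45, 0.28 and 0.61, and DNA replication genes to the left, at -0.14, -0.30 and -0.44.

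The glutathione S-transferases, which conjugate glutathione to reactive and foreign compounds, rose as a group (28 genes, median 0.44, adjusted p = 4.36e-11, and adjusted p = 0.475 with an estimated correlation). Of the 28, 24 had a higher mean after Enigma RNAi and 21 were higher in all 3 pairs. Adjusted over the list alone, 20 rose and 1 fell with the block, against 2 that rose when adjusted over all genes tested, GstD2 and GstD10. GstD5 differed by 1.75 ± 0.77 (SE) without passing, and by 0.86 without control 3. The eIF4A difference between the transcript ends, an RNA quality sign, was higher by 0.33 in the same arrays. The medians differed between classes: 0.95 over 10 GstD genes, 0.51 over 10 GstE genes and 0.10 over the 8 of other classes, a difference between classes that was not tested. GstD genes lie in a cluster of related sequences, so their probe sets are open to cross-hybridisation and the values of single members are uncertain.

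The cytochrome P450s and UDP-glycosyltransferases, enzymes that oxidise or glycosylate lipophilic compounds, rose as a group (31 genes, median 0.29, adjusted p = 1.40e-05, and adjusted p = 0.475 with an estimated correlation). Without control 3 the median was 0.09. Of the 116 list genes on the array only these 31 were tested, so the rise does not cover the rest. Of the 31, 22 had a higher mean and 16 were higher in all 3 pairs. The pair medians were 0.19, 0.08 and 0.52, and after cyclic loess pair 2 lay 0.08 above all genes. With the block, 11 rose and 1 fell when adjusted over the list alone, against 3 that rose when adjusted over all genes tested, Ugt302K1, Cyp6d4 and Ugt37C2, while Ugt49C1 differed by 1.60 ± 0.67 (SE) without passing. The list also took 2 cyclophilins, Cyp1 and Cyp40, through their symbols. Without them the median over 29 genes was 0.34 (adjusted p = 6.21e-07, and adjusted p = 0.468 with an estimated correlation).

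DNA replication genes fell as a group (27 genes, median -0.31, adjusted p = 5.20e-07, and adjusted p = 0.475 with an estimated correlation), and so did mitosis genes (20 genes, median -0.31, adjusted p = 2.38e-07, and adjusted p = 0.475 with an estimated correlation). The median of the replication genes was -0.19 without control 3, and that of the mitosis genes -0.20 without Enigma 2. Of the replication genes 26 of 27 had a lower mean and 20 were lower in all 3 pairs, and of the mitosis genes 20 of 20 and 15. Adjusted over the list alone, 9 replication and 9 mitosis genes fell with the block, against 1 and 0 when adjusted over all genes tested. Mcm3 was that gene. The large subunit of chromatin assembly factor 1 differed by -0.59 ± 0.16 (SE), Incenp, of the chromosomal passenger complex, by -0.71 ± 0.22 (SE), and the cyclin CycB3 by -0.63 ± 0.32 (SE), or -0.34 without control 3, none passing. In the same arrays the eIF4A difference between the transcript ends was higher by 0.33.

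The other lists that passed had smaller medians. Cytosolic heat shock proteins rose as a group (6 genes, median 0.27, adjusted p = 0.0127, and adjusted p = 0.475 with an estimated correlation), with the small heat shock protein Hsp27, which rose with the block, at 0.69 and Hsp26 at 0.44, which was 0.21 without control 1 and 0.71 without control 2. Their median was 0.18 without Enigma 3 and 0.42 without Enigma 1. With the block 3 of the 6 rose when adjusted over the list alone, against 1 over all genes tested. Lipid synthesis and storage genes rose as a group (17 genes, median 0.09, adjusted p = 0.0127, and adjusted p = 0.475 with an estimated correlation), and their median was -0.02 without control 1 and 0.16 without control 2. The fatty acid desaturase Desat1 differed by 0.51, or 0.31 without Enigma 3, the acyl-CoA synthetase bgm, with a control mean of 3.81 under the filter, by 0.30 with a floor at 4, and 1 rose with the block when adjusted over the list alone, against 0 over all genes tested. Serine, one-carbon and amino-acid response genes rose as a group (16 genes, median 0.06, adjusted p = 0.0391, and adjusted p = 0.475 with an estimated correlation). Its members with the largest differences were the glutamine synthetases Gs1 at 0.98, which was 0.11 without control 3, and Gs2 at 0.81, and the median was 0.11 without control 1 and 0.10 without Enigma 2. Of this list 1 rose and 1 fell with the block when adjusted over the list alone, against 1 that rose over all genes tested.

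Mitochondrial ribosomal proteins fell as a group without the block (66 genes, median -0.08, adjusted p = 0.0312, and adjusted p = 0.817 with an estimated correlation) and did not pass with it (adjusted p = 0.0593). Of the 66, 51 had a lower mean, with mRpL9 at -0.53 and mRpL32 at -0.41, which was -0.089 without Enigma 2 and -0.67 without Enigma 1, and 0 passed with the block, adjusted over the list alone or over all genes tested. These 4 smaller calls were lost without single arrays. The adjusted p for heat shock proteins was 0.0812 without control 1, 0.0892 without Enigma 2 and 0.0503 without Enigma 3, and for lipid genes 0.457 without control 1 and 0.0908 without Enigma 3. For serine, one-carbon and amino-acid genes it was 0.0673 without control 2, 0.460 without control 3, 0.0827 without Enigma 1 and 0.166 without Enigma 3, and for mitochondrial ribosomal proteins 0.103 without control 1, 0.119 without control 3 and 0.867 without Enigma 2, with medians of -0.04 without Enigma 2 and -0.13 without Enigma 1. They were also lost under other filters, normalizations or array weights, with adjusted p up to 0.0608, 0.106, 0.162 and 0.391 in that order. With the block, the call for lipid genes was lost without replicate 1 (adjusted p = 0.147), and that for serine, one-carbon and amino-acid genes without replicate 3 (adjusted p = 0.642), with a mean log2 of at least 6 (adjusted p = 0.0582) and with quantile normalization (adjusted p = 0.0893). Mitochondrial ribosomal proteins passed with the block without replicate 1 (adjusted p = 0.0402, and adjusted p = 0.977 with an estimated correlation) and with no filter (adjusted p = 1.78e-05, and adjusted p = 0.689 with an estimated correlation).

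Energy metabolism lists did not pass without the block. The oxidative phosphorylation list had a median of -0.09 over 57 genes (adjusted p = 0.0730), with ND-MWFE at -0.46 and UQCR-6.4 at -0.39, and it passed with the block (adjusted p = 0.0296, and adjusted p = 0.923 with an estimated correlation). That call was lost with a mean log2 of at least 6 (adjusted p = 0.111), with cyclic loess (adjusted p = 0.101), and without replicate 1 or 2 (adjusted p = 0.170 and 0.348). Glycolysis had a median of 0.15 over 8 genes (adjusted p = 0.383), with Pglym78 at 0.25 and Eno at 0.23, and it also passed with the block (adjusted p = 0.0406, and adjusted p = 0.657 with an estimated correlation). This call was lost with a mean log2 of at least 6 (adjusted p = 0.0529), with quantile normalization (adjusted p = 0.0893), and without replicate 1 or 3 (adjusted p = 0.442 and 0.0727). The direction of the oxidative phosphorylation test turned without control 1 and without Enigma 2, and that of glycolysis without control 1. The oxidative phosphorylation median was -0.014 without Enigma 2, -0.032 without control 1, -0.15 without control 2, -0.14 without control 3 and -0.19 without Enigma 1. The glycolysis median was -0.25 without control 1, -0.013 without Enigma 2, -0.032 without Enigma 3, 0.36 without control 2, 0.35 without control 3 and 0.46 without Enigma 1. With each array left out in turn, ND-MWFE ran from -0.73 to -0.20, UQCR-6.4 from -0.53 to -0.24, Pglym78 from -0.22 to 0.65 and Eno from -0.12 to 0.50. Without the block, oxidative phosphorylation also passed without control 2, control 3 or Enigma 1 (adjusted p = 0.00612, 0.00373 and 0.000154, and adjusted p = 0.825, 0.833 and 0.648 with an estimated correlation). It did so with no filter (adjusted p = 0.00228, and adjusted p = 0.742 with an estimated correlation) and with quantile normalization (adjusted p = 0.0301, and adjusted p = 0.835 with an estimated correlation). Glycolysis passed without Enigma 1 (adjusted p = 0.00733, and adjusted p = 0.648 with an estimated correlation). Fatty acid beta-oxidation, the pathway of the acyl-CoA dehydrogenases, had a median of -0.11 over 16 genes (adjusted p = 0.383), against -0.03 over all tested probe sets. Of the 16, 11 had a lower mean, and the list did not pass with the block (adjusted p = 0.247). Its median was -0.053 without control 1, -0.069 without control 3, -0.068 without Enigma 1, -0.051 without Enigma 2 and -0.19 without Enigma 3. With the block and no filter it passed over 20 genes in the lower direction (adjusted p = 0.0390, and adjusted p = 0.618 with an estimated correlation). Its members named are Echs1 at -1.10 and scu, a hydroxyacyl-CoA dehydrogenase, at -0.42, and 3 fell with the block when adjusted over the list alone, against 1 over all genes tested. The TCA cycle list had a median of -0.05 and a mean of 0.03 over 13 genes, with Ogdh at 0.75 and muc, of the pyruvate dehydrogenase complex, at 0.55. Its median ran from -0.086 to -0.0041 with each array left out in turn, and muc from 0.32 to 0.86.

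Of the stress and immune lists other than cytosolic heat shock proteins, none passed with or without the block under the filter used. JNK signalling passed in the higher direction with the block and a mean log2 of at least 6 (adjusted p = 0.0335, and adjusted p = 0.678 with an estimated correlation). Medians were 0.06 over 15 genes of oxidative stress defence, with Gclc at 0.54 and catalase (Cat) at -0.36, -0.05 over 11 mitochondrial chaperones and proteases, with Spg7 at -0.37 and ClpX at -0.26, and -0.08 over 14 genes of the endoplasmic reticulum stress response, with wfs1 at 0.56 and Hsc70-3 at -0.37. Toll and Imd signalling had a median of 0.07 over 14 genes, with spz at 0.66 and pll at -0.53. JNK signalling had one of 0.06 over 11, with wgn at -0.82 and Gadd45 at 0.78, both past the threshold with the block. Apoptosis had one of 0.02 over 9, with Strica at 0.44 and Dredd at -0.44. Antimicrobial peptides and peptidoglycan recognition proteins had 2 genes above the filter, PGRP-LF at 0.11 and PGRP-LE at -0.09, and JAK-STAT signalling 3, with a median of 0.03, Tep4 at 0.80 and dome at -0.05, too few for a test. With each array left out in turn, the medians ran from -0.033 to 0.092 for oxidative stress defence, -0.11 to 0.064 for mitochondrial chaperones, -0.13 to -0.020 for endoplasmic reticulum stress, 0.024 to 0.17 for Toll and Imd, -0.00054 to 0.11 for JNK, -0.046 to 0.090 for apoptosis and 0.0088 to 0.38 for JAK-STAT. Over the same 6 settings, single genes ran from 0.023 to 0.92 for Gclc, -0.47 to -0.17 for Cat, -0.57 to -0.15 for Spg7 and -0.46 to -0.15 for ClpX. The ranges were 0.14 to 0.86 for wfs1, 0.10 to 1.03 for spz, -0.73 to -0.29 for pll, -0.56 to -0.29 for Dredd and 0.26 to 1.13 for Tep4, and PGRP-LF, PGRP-LE and dome took both signs. Of the 2 past the threshold with the block, Gadd45 was at 0.45 without control 3, and wgn at -0.45 without control 1 and -1.25 without Enigma 1.

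In the lists of protein synthesis and turnover, medians were -0.06 over 35 cytosolic ribosomal proteins, with RpL23 at -0.38 and RpL3 at -0.21, -0.06 over 26 aminoacyl-tRNA synthetases, with SerRS-m at -0.50 and TrpRS at 0.26, -0.04 over 27 proteasome genes, with Rpt4 at 0.29 and Pomp at 0.23, and -0.04 over 39 genes of autophagy and the lysosome, with Atg2 at -0.57 and Vha44 at -0.45. Insulin, TOR and FOXO signalling had a median of -0.05 over 13 genes, with InR at -0.64 and Pdk1 at 0.50. Notch signalling had one of -0.02 over 12, with H at -0.31 and kuz at -0.25, and the ecdysone response one of -0.06 over 10, with ImpL2 at 0.25 and Hr78 at -0.23. The RNA interference machinery had a median of -0.06 over 10 genes, with Fmr1 at -0.36 and armi at -0.18. Metal handling had one of 0.01 over 9, with the ferritin subunits Fer2LCH at 0.50 and Fer1HCH at 0.36. Cell adhesion, matrix and actin had one of -0.01 over 18, with SPARC at -0.37 and LanB2 at -0.34, and the peroxisome one of 0.02 over 10, with Pex5 at -0.32 and Pex19 at -0.21. None of these lists passed with or without the block under the filter used. With no filter the cytosolic ribosomal proteins passed in the lower direction, without the block (adjusted p = 0.00482, and adjusted p = 0.558 with an estimated correlation) and with it (adjusted p = 0.0202, and adjusted p = 0.618 with an estimated correlation). With each array left out in turn, their medians stayed between -0.13, for the ecdysone response, and 0.096, for metal handling. That of the peroxisome was below 0 in all 6 settings, and those of the proteasome, autophagy, insulin, ecdysone and cell adhesion lists took both signs. Over the same settings, single genes ran from -0.35 to -0.13 for RpL3, -0.029 to 0.53 for Pomp, -0.78 to -0.13 for Vha44, -0.80 to 0.14 for H, -0.36 to -0.067 for kuz, -0.11 to 0.50 for ImpL2, -0.36 to -0.041 for Hr78, -0.51 to -0.15 for Fmr1 and -0.36 to -0.026 for armi. They ran from -0.82 to 0.045 for SPARC, -0.46 to -0.14 for Pex5 and -0.28 to -0.069 for Pex19. The direction of the test differed in sign from the median for the TCA cycle, mitochondrial chaperones, insulin signalling, proteasome, Notch, cell adhesion and peroxisome lists. Camera compares the mean test statistic of a list with that of the other genes tested, not its median with 0. The median over all tested probe sets was -0.03, below those of the Notch and cell adhesion lists. For the other lists this offset does not account for the direction, which need not follow a median. The mean difference was 0.03 for the TCA cycle and -0.06 for the peroxisome, against medians of -0.05 and 0.02.

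Of the cell type markers, only the plasmatocyte list had enough genes for a test. Its median was 0.09 over 6 genes, without passing (adjusted p = 0.343, and adjusted p = 0.614 with an estimated correlation), and the plasmatocyte gene Hml, chosen after its value was seen, was expressed at 11.01 in controls and 10.86 after Enigma RNAi. With each array left out in turn the list's median ran from -0.18 to 0.21. Medians of the others were -0.05 for 1 crystal cell gene, 0.19 for 3 lamellocyte genes, 0.03 for 1 fat body gene, 0.07 for 4 muscle genes, -0.03 for 2 neuronal genes, -0.08 for 1 glial gene, -0.03 for 2 germline genes and -0.02 for 1 gene of imaginal epithelium, and 0 gut genes passed the filter. Over the same settings the median ran from -0.11 to -0.0097 for crystal cell, 0.016 to 0.35 for lamellocyte and 0.024 to 0.11 for muscle genes. Those for fat body, neuron, glia, germline and imaginal epithelium took both signs.

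The arrays differed more by replicate number than by treatment. Of the sum of squares over tested probe sets, 67.6% lay between replicate numbers and 20.1% between groups. The shares are not on an equal footing, since the replicate number has more levels than the treatment and a factor without effect also takes a share. The first principal component, with 43.8% of the variance, set the arrays numbered 1 apart from the other 4. The median of the tested probe sets was 6.14 ± 0.02 in controls and 6.06 ± 0.07 after Enigma RNAi (SD, n = 3), and the spike-in controls averaged 9.69 ± 0.13 and 9.41 ± 0.14.

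**Figure D3:**
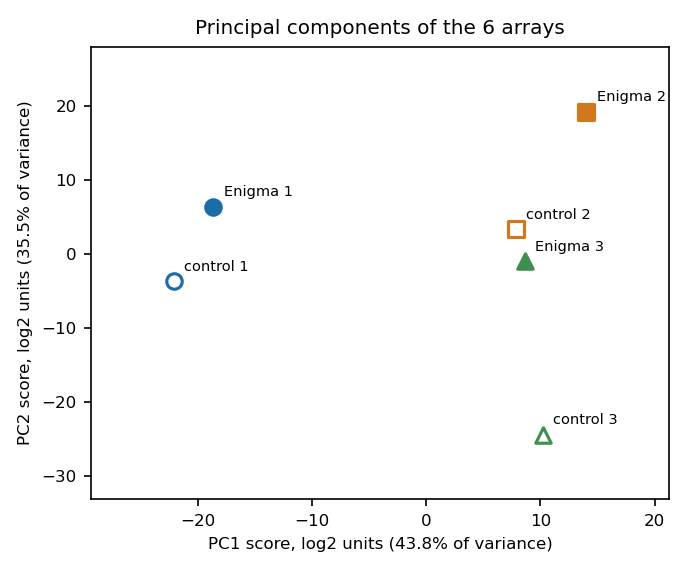
Scores of the 6 arrays on the first and second principal components of the tested probe sets, in log2 units, with open symbols for control RNAi, filled symbols for Enigma RNAi and a colour and shape for each replicate number. Both arrays numbered 1 lie at the left, at -22.10 and -18.63 on the first component, apart from the other 4.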

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

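The settings that combine the block with another choice, the random block, the P450 list without cyclophilins and the estimated correlation in settings other than the unblocked one were chosen after the results were seen, and the other settings before. Without the block, 0 probe sets passed in all 11 processing settings and with each of the 6 arrays left out, with 159 to 470 and 147 to 416 at an unadjusted p under 0.05. The log2 difference of Enigma stayed between -2.72 and -2.31 across 8 processing settings (adjusted p from 0.0655 to 0.722) and between -3.002 and -2.52 without single arrays. With the replicate block, 44 passed, 25 higher and 19 lower, and Enigma, at -2.72, was among them. With the block and another choice, the total, higher and lower counts were 1, 0 and 1 with no filter, 1, 0 and 1 with quantile normalization, 1, 0 and 1 with cyclic loess, 95, 53 and 42 with a mean log2 of at least 6, and 140, 76 and 64 with trend and robust estimation. Enigma passed in each of these settings, at -2.72 with an adjusted p from 7.06e-06 to 0.0217. With the block, the counts were 586, 243 and 343 without replicate 1, 2, 1 and 1 without replicate 2, and 8, 7 and 1 without replicate 3, with Enigma at -2.71, -2.63 and -2.83. The random block called 3, 2 higher and 1 lower. The gene lists passing numbered 8, with 4 at a mean log2 of at least 6, 5 to 9 without single arrays, and 0 with fry or, in every setting where it was estimated, with an estimated correlation (smallest adjusted p 0.238), against 12 with the block and no filter. The cause of these differences was not tested, except that leaving out arrays leaves fewer samples and a filter changes how many probe sets are tested. With the block, leaving out a replicate also leaves fewer residual degrees of freedom. That fit depends strongly on the variance that eBayes shares across probe sets, so 586 without replicate 1 does not measure a gain in changed genes. Of the list calls, the block ended that of mitochondrial ribosomal proteins and added those of oxidative phosphorylation and glycolysis, and it changed no other. The glutathione S-transferases, P450s with UDP-glycosyltransferases, DNA replication and mitosis lists passed with the preset correlation in every processing setting and without every single array, the highest adjusted p being 0.00517. Of the 96 named genes besides Enigma, 28 passed with the block, 45 moved by over 1.5 times without 1 of the arrays, and 10, none passing, changed sign in a setting. PGRP-LF was -0.063 with array weights, dome 0.023 with median centring, and with the block and without replicate 2 dome was 0.013 and armi 0.0067. Without single arrays PGRP-LF ranged from -0.069 to 0.23, dome from -0.11 to 0.017, PGRP-LE from -0.24 to 0.062, Pglym78 from -0.22 to 0.65, Eno from -0.12 to 0.50, H from -0.80 to 0.14, ImpL2 from -0.11 to 0.50, SPARC from -0.82 to 0.045 and Pomp from -0.029 to 0.53. Signal over background limits what the arrays show, since 6975 of 14010 probe sets reached the filter.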

Other observations

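Of the tests reported here, the share of variance between replicate numbers after cyclic loess was set before its result was seen, and the other tests were chosen after the results were seen. The arrays numbered 1 stood apart from those numbered 2 and 3. Each number was compared with the other arrays together, with the treatment in the model. For number 1, 318 probe sets differed (limma, 183 higher and 135 lower). For number 2 and number 3, 0 and 0 passed, while 1219 and 831 had an unadjusted p under 0.05. When number 2 or 3 was tested, the arrays numbered 1 were among the others and added to the spread there. The 0 calls therefore do not show that numbers 2 and 3 do not differ. Glycolysis genes were lower in the arrays numbered 1 (8 genes, median -1.10, adjusted p = 1.17e-08 with the preset correlation, and adjusted p = 0.549 with an estimated correlation), and 6 of the 8 were past the threshold singly, Pgi at -0.99 and Hex-A at -0.19 not among them. Phosphofructokinase (Pfk) was at -2.49 and phosphoglycerate kinase (Pgk) at -1.29. Outside the lists, Glyp, AGBE and Pgm1 were lower as well, at -1.96, -1.79 and -2.03. Oxidative phosphorylation genes were higher there (57 genes, median 0.31, adjusted p = 1.94e-07, and adjusted p = 0.999 with an estimated correlation), as were the collagen gene Col4a1 at 2.11 and the peroxidase gene Pxt at 1.89. The genes named for this difference were chosen after their values were seen. Other lists differed by replicate number too: of 29 lists, 2, 6 and 3 passed with the preset correlation for numbers 1, 2 and 3, and 0 with an estimated correlation. In the arrays numbered 2, the glutathione S-transferases (median 0.32, adjusted p = 0.0242) and the P450s with UDP-glycosyltransferases (0.18, adjusted p = 0.0175) were higher, while mitosis (-0.19, adjusted p = 0.0242) and oxidative phosphorylation genes (-0.22, adjusted p = 1.96e-05) were lower, each with an adjusted p = 0.706 with an estimated correlation. In those numbered 3, DNA replication and mitosis genes were higher (medians 0.25 and 0.27, adjusted p = 0.000594 for both, and adjusted p = 0.784 with an estimated correlation).

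For this difference by replicate number, 67.9% of the sum of squares lay between replicate numbers after cyclic loess, against 67.6% before it. Cyclic loess was run on values that GCRMA had already normalized and could not undo that step. Normalization between arrays therefore stays open as a cause. RNA integrity stays open: the mean difference between transcript ends was higher by only 0.025 in the arrays numbered 1. Its 95% interval, -0.34 to 0.39 from a linear model with the treatment, takes in a difference as large as the 0.19 between treatments. For Gapdh alone both arrays numbered 1, at 2.121 and 2.066, lay above the other 4, the highest at 2.063. The Gapdh difference was 0.11 with an interval of -0.07 to 0.29. For eIF4A and actin the arrays numbered 1 differed by 0.05 and -0.08. A first version asked whether these arrays lay within the range of the others in the mean and would have counted against RNA integrity, and it was replaced after its result was seen because lying within a range excludes nothing. Lower oxygen in the cultures numbered 2 and 3 is a candidate explanation that stays open as well: the median difference of 3 low-oxygen genes outside glycolysis was -0.14, at percentile 14.8 of 10000 random lists matched on expression, which would have counted against it until a minimum of 5 genes was required after that value was seen. The labels give no batch or day, and the design names no biological explanation for this pattern.

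The rise of the glutathione S-transferases could come from the treatment, from RNA quality or from chance variation between arrays, which cannot be told apart here. The list did not pass in camera with an estimated correlation (adjusted p = 0.475) or in fry (adjusted p = 0.549). After cyclic loess the smallest pair median was 0.36 above all genes, so the rise was not shared by all genes. Cyclic loess followed GCRMA and could not undo its normalization, which stays open as a cause. The median over the 18 genes outside the GstD cluster was 0.29, above all 10000 random lists matched on expression. Those lists held unrelated genes and left out correlation within the family. They cannot decide whether signal shared within the GstD cluster was the cause. For RNA integrity, pair 1, where the ends of the control transcripts changed least, had a median of 0.45 with a lower 95% bootstrap bound of 0.23, above the 0.21 that scaling pair 3 by the change in RNA quality would give, but pair 2 had a median of 0.28 with a bound of 0.18, below its scaled value of 0.64. Earlier versions rested on pair 1 alone, scaled to 0.09 by the mean ratio and then to 0.21, and would have counted against RNA integrity, and pair 2 was added after they were seen because a single pair excludes nothing. Signal shared among the 10 GstE genes stays open too, since the 8 genes of other classes had a median of 0.10, and whether the loss of Enigma or another difference between the double-stranded RNAs lies behind the rise was not tested.

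The fall of DNA replication and mitosis genes could come from the treatment, from RNA quality or from chance variation between arrays, which cannot be told apart here. Neither list passed in camera with an estimated correlation (adjusted p = 0.475 for both) or in fry (adjusted p = 0.549 for both). After cyclic loess the pair median nearest 0 was -0.15 relative to all genes, so the fall was not shared by all genes. Cyclic loess followed GCRMA and could not undo its normalization, which stays open as a cause. For RNA integrity, pair 1 had a median of -0.16 over 47 genes, with a bootstrap bound of -0.09, and pair 3 scaled by the largest ratio of changes in the control transcripts gave -0.15, past that bound, while pair 2 had a median of -0.31 with a bound of -0.17 against a scaled value of -0.45. A first version, scaled by the mean ratio, gave -0.07 and would have counted against RNA integrity, and the wider scaling and pair 2 were added after it was seen.

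Other groupings of the arrays were counted. The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For probe sets passing without the block, 10 of the 10 splits gave as many as the real one, with 0 in the real split and 0 as the highest of the others. With 0 in the real split this outcome was fixed in advance and shows nothing. Without the block, the other 3 splits that part all 3 pairs had 5, 25 and 20 probe sets at an unadjusted p under 0.05, against 297 in the real one and 348.75 expected by chance for unpaired arrays. For gene lists, 1 of the 10 passed as many, the real split itself, with 8 in the real split and 7 as the highest of the others. With the block, 4 splits part all 3 pairs, again too few, and 1 called as many probe sets, the real split itself, with 44 in the real split and 0 as the highest of the others. Gene lists passing with the block numbered 9 in the real split and 1, 5 and 6 in the other 3. With the block these 3 had 46, 124 and 133 probe sets at an unadjusted p under 0.05, against 1347 in the real one. Without the block, the splits that part only 1 pair had 145, 340, 654, 669, 800 and 848 at an unadjusted p under 0.05, against 297 in the real split. The highest set control 1, control 3 and Enigma 1 apart. All but the split with 145 lay above the real one, which points to the structure by replicate number.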
